A study of Mus musculus with 6 samples.

How the data were processed

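The data are mRNA sequencing libraries from mouse trigeminal ganglion, 3 labelled NC-up and 3 labelled SETDB2-up. Per the labels' protocols, RNA was extracted with TRIzol, enriched for polyadenylated transcripts and made into strand-specific libraries, which were sequenced as paired reads of 150 bp on a NovaSeq instrument. Per the submitters' processing notes, FastQC, HISAT2 and the GRCm38 build were used, with no versions; the read counter, its strand setting, the annotation, the size-factor method and the filter on low genes are not given in the sources used here. The labels give each library's group and number, and the deposited table's columns carry the library names that the labels state.

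The deposited table holds a normalised signal per gene and library: read counts that the authors divided by a single factor per library, as the values show. Within each library every value is a whole multiple of that library's own step, so that 100% of the values came out as whole reads (tolerance 0.001 read), and the column medians lie between 415 and 419.9. The recovered reads sum to 19334997, 21734814 and 23395693 in NC-up libraries 1 to 3 and to 21548941, 20355707 and 23501386 in SETDB2-up libraries 1 to 3. These sums cover the 16415 listed genes only. At this depth 3 reads correspond to 0.128 to 0.155 CPM. The smallest sum over the 6 libraries is 33 recovered reads, and how genes with fewer were left out is not given in the sources used here. Libraries of a group differed beyond sampling noise (chi-square per degree of freedom 3.97 to 9.93). Separate preparations from the same animal could differ in this way too, so the libraries are the unit of the tests and are not shown to be biological replicates. Of the list of mitochondrially encoded messenger RNAs no member is in the table, and it was not analysed here; 14 other genes of the mitochondrial chromosome hold 0.0546% to 0.0692% of the reads.

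The design written before the data were examined named edgeR for counts and, as a fallback, limma for FPKM, RPKM, TPM or CPM. The deposited unit was none of these by name; as the values are normalised, the fallback was used, and edgeR on recovered reads became an alternative. The main test was limma (3.58.1, in R 4.3.3) with a mean-variance trend and without robust settings, on log2(value + 1), over the 16387 genes with a value of at least 1 in at least 3 libraries (28 genes were removed). P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 counts as changed. Fold changes are differences of log2(value + 1) and understate the change of low genes. For named genes without reads in a group, the fold was set against 3 reads over the group's 3 libraries; for 1 to 3 reads, a ratio with an exact (Clopper-Pearson) 95% interval is given. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

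Both tools were run on simulated counts for the same genes and libraries with 200 genes changed. Limma recovered 36% of changes of 1.25-fold, 76% of 1.5-fold, 84% of 2-fold and 96% of 4-fold (50 genes each), with 11 false calls (7.01% of its calls). EdgeR (4.0.16) recovered 36%, 76%, 86% and 96%, with 8 false calls. The changed genes were drawn above a minimum mean value, so the rates do not hold for low genes. Apart from the changes, simulated libraries differed in depth alone, without a GC trend, so the false calls do not carry over to the real data.

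Genes were named by a rule fixed before the data were examined: the 5 genes of the series title; the 10 largest rises and falls past the threshold with at least 1 CPM in a group, no overlap between the groups and a name that is not a placeholder; the 5 smallest p in each direction; and up to 4 members of each list past its threshold and 3 of each other list. Some genes that this rule selects are not reported here. Lists of 53 pathways, gene families and cell type markers were fixed at the same time, and 52 had at least 4 measured members. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists. Neighbours of Ide, zinc-finger genes and a list of 42 liver genes were chosen after values had been seen.

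Transcript GC content and length came from the GENCODE M21 transcripts of GRCm38, matched for 15541 genes (94.7%) by gene identifier or symbol. Of 15346 genes found there by symbol, 15343 overlapped the annotated gene on the same strand, so coordinates are those of the table, in GRCm38. Genes overlapped on the opposite strand by a gene with at least 4 times the reads numbered 1459.

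Alternatives set beforehand were a pseudocount of 0.1, no filter, edgeR on recovered reads with TMM, RLE or upper-quartile factors and other filters, DESeq2 (1.42.0), limma-voom with and without library weights, the replicate number as a block, a 2-fold minimum, and leaving out each library. Added after the data were examined were a GC correction (a loess trend of each library's deviations, span 0.3), GC with length, GC with the block, the genes with a GC value uncorrected, leaving out SETDB2-up libraries 1 and 2, opposite-strand genes or liver genes, and robust limma. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, tests and plots.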

Results

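Messenger RNA was profiled by bulk sequencing of mouse trigeminal ganglion, the sensory ganglion that carries touch, temperature and pain from the head. The labels give all 6 libraries a wild-type genotype and divide them by treatment into 3 named NC-up and 3 named SETDB2-up. They do not spell out either name or say how the treatment was given. Values are read counts per gene, normalised by the authors with a single factor per library. The whole reads recovered from them summed to between 19334997 and 23501386 per library over the 16415 listed genes. The libraries carry numbers within each group, and nothing in the labels says that they came from separate animals, so p-values measure the spread between these libraries.

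The first comparison concerned the genes that the series title places together in sensory neurons in migraine: Setdb2, Klf4, Ide and the genes for CGRP. Setdb2, a member of the histone H3 lysine 9 methyltransferase family (gene 239122, chromosome 14, 59402009 to 59440880, GRCm38), was higher in the SETDB2-up libraries. Its normalised read counts were 69.9, 58.4 and 71.5 in NC-up and 113, 97.6 and 104 in SETDB2-up, with means of 66.6 ± 7.14 and 105 ± 7.72 (SD, n = 3 each). Its log2 fold change was 0.65 ± 0.19 (SE, limma adjusted p = 0.0253). Another listed gene overlaps the Setdb2 locus, but none on the opposite strand has at least 4 times its reads. Klf4, a zinc-finger transcription factor (gene 16600, chromosome 4, 55527137 to 55532475), fell from 198 ± 20.9 to 122 ± 23.6 (SD, n = 3 each), a log2 fold change of -0.71 ± 0.16 (SE; limma adjusted p = 0.00612). Its values were 216, 203 and 175 against 118, 147 and 101. Ide, the insulin-degrading metallopeptidase (gene 15925, chromosome 19, 37268743 to 37334544), fell from 2263 ± 106 to 1303 ± 47.6 (SD, n = 3 each). Its log2 fold change was -0.80 ± 0.06 (SE; limma adjusted p = 1.91e-07), with 2376, 2166 and 2245 in NC-up and 1357.5, 1269 and 1282 in SETDB2-up.

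Calca, which encodes alpha-CGRP and calcitonin (gene 12310, chromosome 7, 114625981 to 114636910), rose from 8011 ± 236 to 9564 ± 318 normalised reads (SD, n = 3 each). The log2 fold change was 0.26 ± 0.05 (SE; limma adjusted p = 0.00335), and all 3 SETDB2-up values (9368, 9393 and 9931) lay above the NC-up values (8203, 7748 and 8082). Calcb, which encodes beta-CGRP (gene 116903, chromosome 7, 114716555 to 114723368), did not pass the test, at 1017, 1109 and 1006.5 against 999, 1005 and 1075 (log2 fold change -0.02 ± 0.07 SE; limma adjusted p = 0.857). As a list fixed before the data were examined, these 5 genes held 2 that rose and 2 that fell, with the same counts adjusted over the list alone. The Setdb2 call was the least secure of them. It was lost without NC-up library 2 (log2 fold change 0.56), SETDB2-up library 1 (0.60), library 2 (0.70) or library 3 (0.66), and after a correction for GC content (0.49 ± 0.19 SE, adjusted p = 0.139); adjusted p ranged from 0.0152 to 0.416 over 26 alternatives. Calls for Klf4, Ide and Calca held in all 26 alternatives, of which 1 leaves a single SETDB2-up library, with a spread that comes from NC-up alone.

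**Figure D1:**
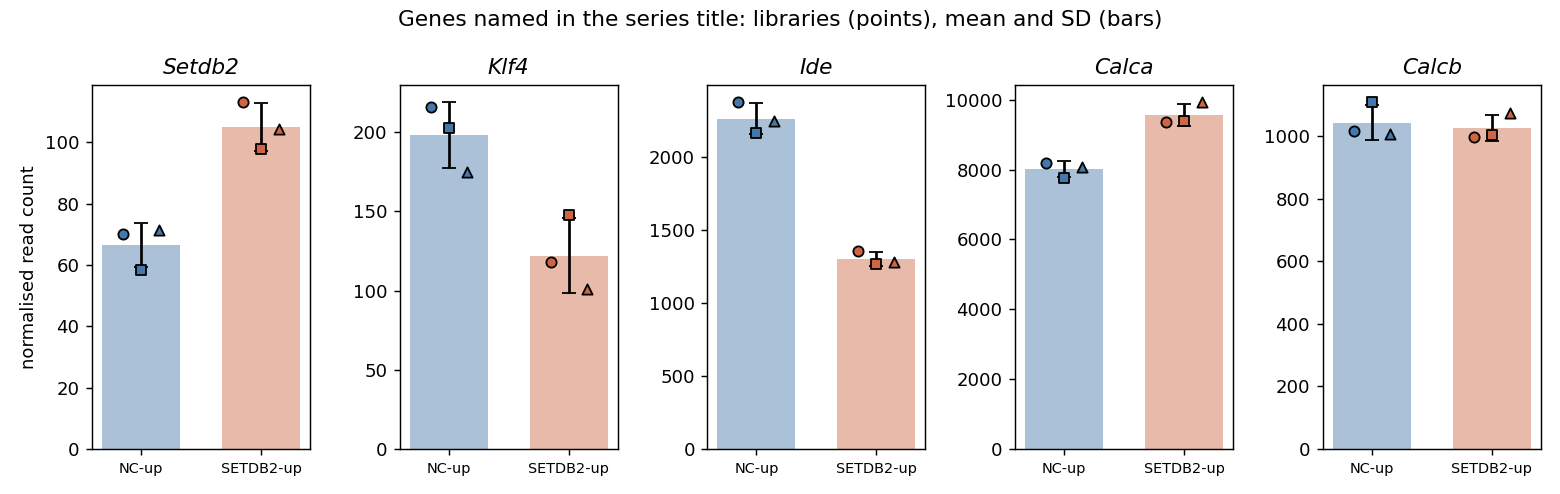
Normalised read counts (y axis, linear from 0) of Setdb2, Klf4, Ide, Calca and Calcb in NC-up (blue) and SETDB2-up (orange) libraries, with bars for the mean, error bars for the SD and circles, squares and triangles for libraries 1, 2 and 3 of each group. Ide lay between 1269 and 1357.5 in the SETDB2-up libraries and between 2166 and 2376 in the NC-up libraries, while the ranges of Calcb overlapped.

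Ide did not fall alone on chromosome 19. Fgfbp3 (36917550 to 36919599), which encodes a secreted binding protein for fibroblast growth factors, fell from 97.4 ± 7.43 to 49.3 ± 5.22 (SD, n = 3 each; log2 fold change -0.97 ± 0.21 SE, limma adjusted p = 0.00383). Btaf1 (36926079 to 37014057), a regulator of the TATA-binding protein, fell from 1076 ± 52.6 to 697 ± 60.6 (log2 fold change -0.63 ± 0.08 SE, limma adjusted p = 5.63e-05). The lncRNA 4931408D14Rik (37258423 to 37264095), which ends just before Ide, fell from 85.4 ± 15.1 to 10.8 ± 2.65 (log2 fold change -2.88 ± 0.32 SE, limma adjusted p = 1.02e-05). Between Btaf1 and 4931408D14Rik lie Cpeb3 (log2 fold change 0.02 ± 0.07 SE) and Marchf5 (-0.08 ± 0.07 SE), which did not pass the test. Of the 16 other measured genes within 1000000 bp of Ide, none fell at an adjusted p under 0.05 and 1, Pcgf5, rose. Hhex (-0.84 ± 0.36 SE, limma adjusted p = 0.117) and Ppp1r3c (-0.58 ± 0.20 SE, limma adjusted p = 0.0563) had low counts and large falls that did not pass. The region was chosen after its values were seen, and Fgfbp3, Btaf1 and 4931408D14Rik are named because they fell.

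**Figure D2:**
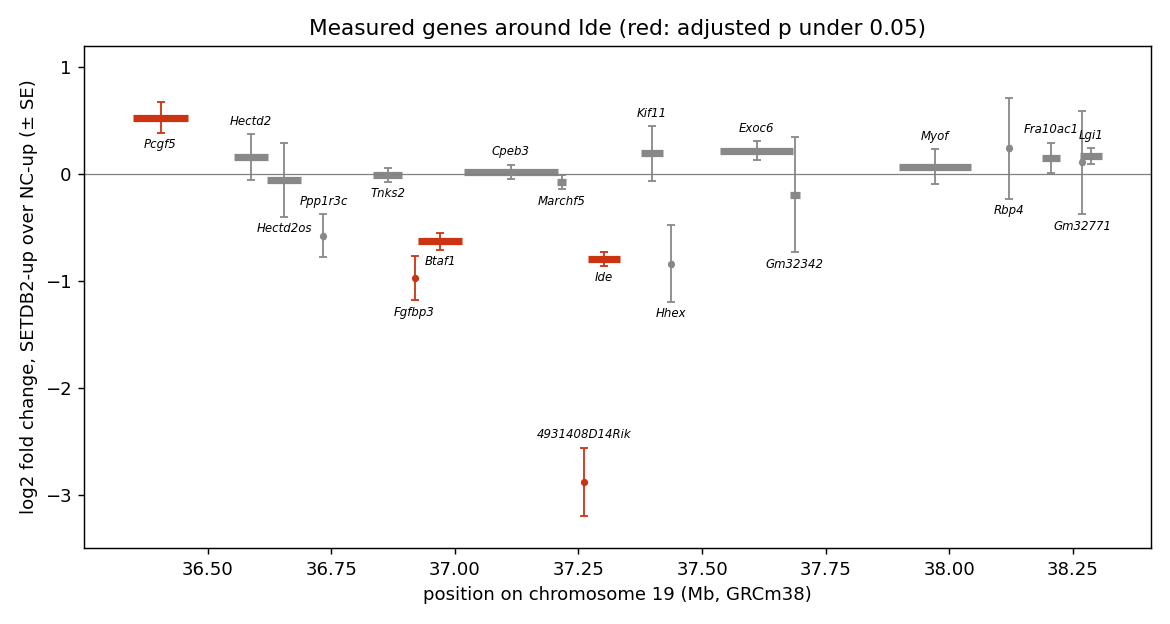
Log2 fold change (y axis, SETDB2-up over NC-up, error bars SE, n = 3 each) of the 20 measured genes within 1000000 bp of Ide, drawn at their positions on chromosome 19 (x axis, Mb), with genes past an adjusted p of 0.05 in red and the others in grey. Ide at -0.80, Btaf1 at -0.63, Fgfbp3 at -0.97 and 4931408D14Rik at -2.88 lie below 0, with Cpeb3 and Marchf5 near 0 between them.

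The second comparison asked which genes changed across the transcriptome. Alb, the gene for serum albumin (chromosome 5, 90460870 to 90476602), had the largest rise: no read in the 3 NC-up libraries against 1673, 3769.5 and 11.6 normalised reads in SETDB2-up libraries 1, 2 and 3. That is at least 1800.4-fold higher, taking 3 reads over the group as the floor. Apob, the main protein of very-low-density lipoproteins (chromosome 12, 7977629 to 8016839), had 450.3, 1159.5 and 3.57 against 0, 2.87 and 0, a ratio of 532 (95% exact counting interval 182 to 2580.4). Serpina1d was at least 86.4-fold higher, and Plg (plasminogen) and Hrg had ratios of 116 (20.5 to 4632) and 33.0 (8.79 to 278). Pzp and Fgg were also among the 10 largest rises, of which 8 were genes that liver expresses strongly, and their reads sat mostly in SETDB2-up libraries 1 and 2. Rn7sk, a small nuclear RNA, followed those libraries too, with 170.05, 451.6 and 27.7 against 5.30, 19.2 and 9.83. Plin4, a lipid-droplet protein, completed the 10 (log2 fold change 1.51 ± 0.38 SE, limma adjusted p = 0.00990), with 180, 142 and 245 (24.4, 83.3 and 129 in NC-up). Serpina1d has near-identical family members and Plin4 lies under Hdgfl2 on the opposite strand, so their reads are uncertain. In edgeR on recovered reads Alb (log2 fold change 13.88, adjusted p = 0.320), Pzp (4.69, 0.131), Fgg (2.44, 0.163), Rn7sk (4.20, 0.130) and Plin4 (1.24, 0.257) did not pass. Their folds there were larger than in limma for all but Plin4. Calls were lost in 7 alternatives for Alb, 7 for Pzp, 10 for Fgg, 8 for Rn7sk and 8 for Plin4.

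**Figure D3:**
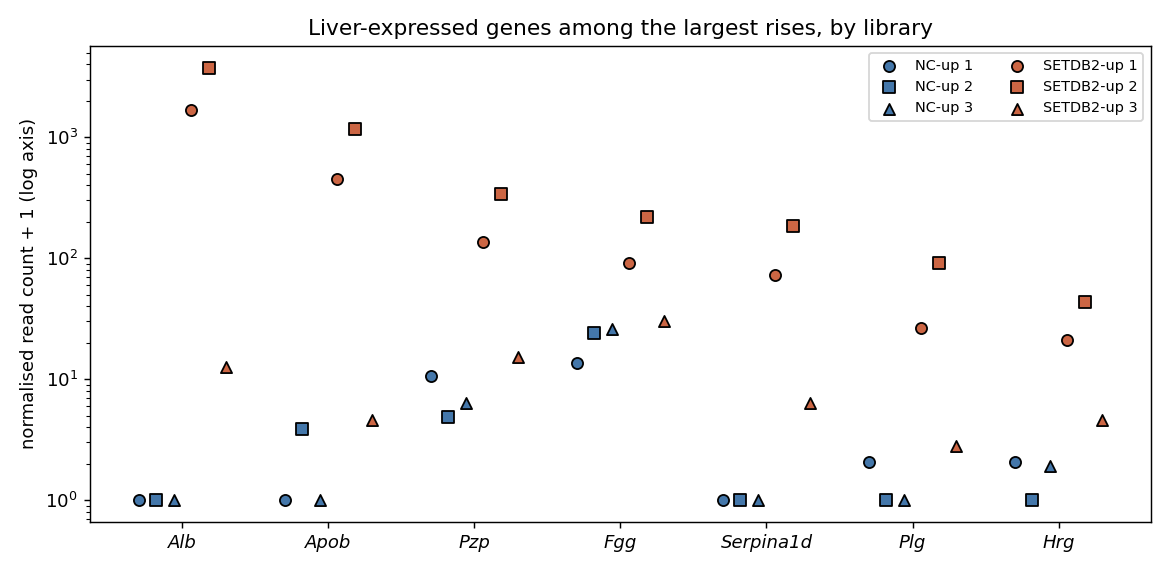
Normalised read counts plus 1 (y axis, log scale) of liver-expressed genes in each NC-up (blue) and SETDB2-up (orange) library, with circles, squares and triangles for libraries 1, 2 and 3. Alb reached 1673 and 3769.5 in SETDB2-up libraries 1 and 2 and 11.6 in library 3, with no read in the NC-up libraries.

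Bc1, a short brain cytoplasmic RNA of neurons (chromosome 7, 144914470 to 144914623), had the largest fall, from 1011 ± 113 to 39.0 ± 22.8 (SD, n = 3 each; log2 fold change -4.89 ± 0.32 SE, limma adjusted p = 1.19e-08). The keratinocyte genes Krt14 and Lor fell: Krt14 had 96 recovered reads against 3, a ratio of 0.0308 (95% exact counting interval 0.00624 to 0.0928), with NC-up libraries at 2.12, 51.7 and 35.8, so that the ratio rests on NC-up libraries 2 and 3, and Lor had a log2 fold change of -2.23 ± 0.36 SE. The muscle genes Acta1 (-2.07 ± 0.55 SE) and Atp2a1 (-1.68 ± 0.34 SE) fell as well, at low counts. Hba-a2, an alpha-globin gene, fell from 1425 ± 540 to 433 ± 272 (SD, n = 3 each; log2 fold change -1.83 ± 0.27 SE), while its near-identical copy Hba-a1 did not pass (-0.12, limma adjusted p = 0.789), so the split of reads between them is uncertain, and Hba-a2 did not pass in edgeR (log2 fold change -1.71, adjusted p = 0.135). C1ql1, Baiap3, Capn12 and Ifitm7 made up the 10 largest falls, with log2 fold changes from -1.79 to -1.37. After GC correction Krt14 (-3.21, adjusted p = 0.0567) and C1ql1 (-1.40, 0.0967) did not pass, though their folds stayed large, and they lost their calls in 5 and 6 alternatives. Atp2a1, Baiap3, Capn12 and Ifitm7 each lie under a gene on the opposite strand with at least 4 times the reads. Bc1 (168 bases) and Rn7sk (331 bases) are short transcripts, and these libraries were enriched for polyadenylated RNA. Whether that selection or the fragment length affected their counts was not tested.

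Among the genes with the smallest p, Cdr1 (chromosome X, 61183246 to 61185558, minus strand) rose from 394 ± 61.1 to 835 ± 24.5 (SD, n = 3 each). Its log2 fold change was 1.09 ± 0.10 (SE, limma adjusted p = 1.07e-06). The imprinted gene Ndn (chromosome 7, 62348277 to 62349928) rose from 2165 ± 76.3 to 3428 ± 247 (log2 fold change 0.66 ± 0.06 SE), and Cdh19, a cadherin of Schwann-lineage glia, from 888 ± 28.0 to 1432 ± 66.8 (0.69 ± 0.07 SE). Zmym2 rose by 0.59 and the ubiquitin pseudogene Ubb-ps by 1.19 on the log2 scale, the latter with reads that its parent gene Ubb could share. Eno3, muscle enolase (chromosome 11, 70653125 to 70662513), fell from 1807 ± 107 to 836 ± 22.9 (SD, n = 3 each; log2 fold change -1.11 ± 0.07 SE, limma adjusted p = 9.43e-09), and overlaps Pfn1. The unnamed loci Gm46526 (-2.25), Gm36629 (-1.78) and LOC115488529 (-2.19) fell too. They lie opposite Sult4a1, B3gat3 and Zfp706, so whether their reads belong to them depends on how strand was counted, which is not given in the sources used here.

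In all, 2690 of 16387 tested genes changed (limma adjusted p under 0.05), 1263 upward and 1427 downward. The median size was a 1.26-fold change. Of the 2690, 176 changed by at least 2-fold (46 up, 130 down). This downward excess was absent without genes under a more abundant opposite-strand gene, where 83 changed by at least 2-fold (41 up, 42 down). Those 41 rises still included liver genes such as Alb and Apob. Without liver genes 28 rose and 132 fell by at least 2-fold. The 2 sets of genes were not removed together, so whether a downward excess remains without both was not tested. Without SETDB2-up library 1 the count was 1093, without SETDB2-up library 2 it was 1573, without NC-up library 2 it was 1611, and without both SETDB2-up libraries that hold liver transcripts, which leaves 1 library in that group, it was 540. Fold changes followed base composition: in the lowest decile of GC content 419 genes rose and 23 fell, and in the highest decile 5 rose and 529 fell. After a GC correction chosen once this was seen, 957 genes changed, 337 upward and 620 downward, of which 696 were among the 2690.

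**Figure D4:**
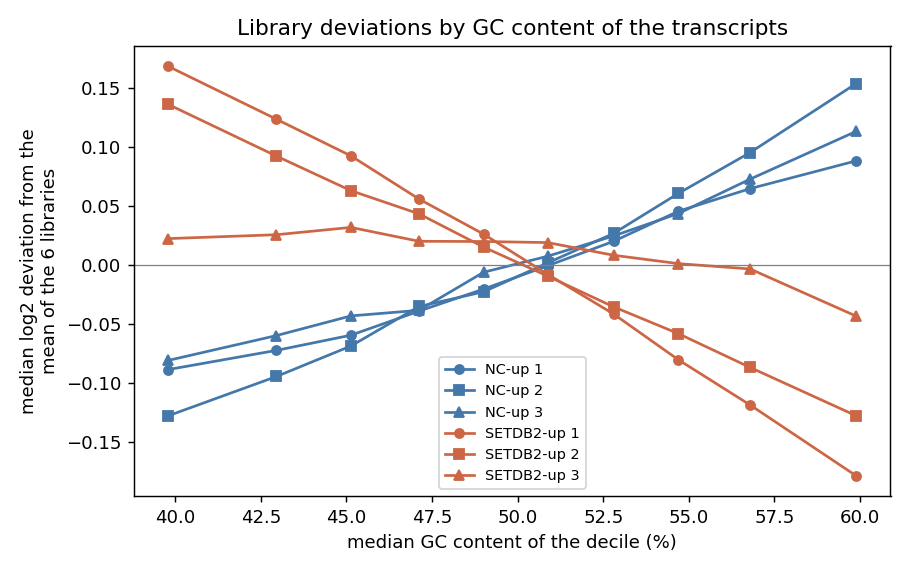
Median log2 deviation of each library from the mean of the 6 libraries (y axis) in deciles of genes ordered by transcript GC content (x axis, median percent), for NC-up (blue) and SETDB2-up (orange) libraries 1 (circles), 2 (squares) and 3 (triangles). In the highest decile the NC-up libraries lay between 0.09 and 0.15 and the SETDB2-up libraries at -0.18, -0.13 and -0.04.

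Gene lists fixed before the data were examined were then tested, 52 of them with at least 4 measured members. In the extracellular matrix list 13 of 34 members fell and 1 rose (15 and 2 adjusted over the list alone), among them the collagens Col1a1 (-0.55 ± 0.08 SE), Col5a1 (-0.53 ± 0.08 SE) and Col1a2 (-0.35 ± 0.06 SE), while the proteoglycan Ogn rose (0.52 ± 0.06 SE). In the fibroblast list 9 of 21 fell and 1 rose (the same adjusted over the list alone), including Igf2, a growth factor (-0.87 ± 0.09 SE), and Mgp, an inhibitor of calcification (-0.55 ± 0.10 SE); both lists hold Col1a1 and Col1a2. The other 20 matrix and 11 fibroblast genes did not pass. Each had an adjusted p of 0.000633 by camera with a preset correlation, against adjusted p = 0.840 with an estimated correlation. After GC correction 8 matrix genes fell and 1 rose, and 6 fibroblast genes fell.

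In the heat shock list 5 of 15 rose and none fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00964, against adjusted p = 0.840 with an estimated correlation): Hspa8 went from 39904 to 51670.0 normalised reads (log2 fold change 0.37 ± 0.06 SE), with Hsp90aa1 (0.36 ± 0.05 SE), Hspd1 (0.37 ± 0.06 SE) and Dnaja1 (0.34 ± 0.05 SE), all of them chaperones or co-chaperones. After GC correction 5 rose. In the immediate early list 5 of 20 fell and none rose (the same adjusted over the list alone; camera adjusted p = 0.0155, against adjusted p = 0.840 with an estimated correlation), including the transcription factors Nr4a3 (-1.19 ± 0.28 SE), Egr3 (-0.72 ± 0.14 SE), Nr4a1 (-0.46 ± 0.09 SE) and Jun (-0.35 ± 0.06 SE); the list missed the threshold after GC correction (adjusted p = 0.0616), where 4 fell. In the glucocorticoid list 5 of 16 fell and none rose (the same adjusted over the list alone; camera adjusted p = 0.00759, against adjusted p = 0.840 with an estimated correlation). These included Ddit4, an inhibitor of mTOR signalling (-0.70 ± 0.08 SE), the cell cycle inhibitor Cdkn1a (-0.47 ± 0.06 SE), the clock gene Per1 (-0.47 ± 0.11 SE) and Cebpd (-0.37 ± 0.11 SE). After GC correction 3 fell, without Per1 (-0.26, adjusted p = 0.164) and Cebpd (-0.34, 0.0732), and Per1 did not pass in edgeR (-0.49, 0.117); they lost their calls in 12 and 7 alternatives. In the list of nuclear genes for oxidative phosphorylation 14 of 65 fell and 3 rose (17 and 3 adjusted over the list alone; camera adjusted p = 0.00964, against adjusted p = 0.840 with an estimated correlation), led by the small subunits Atp5k (-0.66 ± 0.09 SE), Uqcr11 (-0.64 ± 0.08 SE) and Ndufa3 (-0.60 ± 0.08 SE) and by Ndufs7 (-0.44 ± 0.07 SE). After GC correction 13 fell and 1 rose.

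In antigen presentation 5 of 20 fell and none rose (the same adjusted over the list alone; camera adjusted p = 0.00759, against adjusted p = 0.840 with an estimated correlation), among them the peptide-loading genes Tap1 (-0.65 ± 0.17 SE) and Tapbp (-0.37 ± 0.07 SE), H2-DMa (-0.32 ± 0.10 SE) and Psmb10 (-0.33 ± 0.11 SE), and none passed singly after GC correction (-0.52, -0.22, -0.22 and -0.19). H2-DMa lies opposite the more abundant Brd2. Psmb10 lost its call in 9 alternatives, H2-DMa in 8, Tap1 in 6 and Tapbp in 3. NC-up library 1 was the highest for Tap1 (442 against 259 and 271) and Tapbp (3179 against 2671 and 2619). In the type I interferon list 2 of 35 fell, Oasl1 (-0.92 ± 0.29 SE) and Rsad2 (-0.56 ± 0.18 SE), and none adjusted over the list alone (camera adjusted p = 0.0290, against adjusted p = 0.840 with an estimated correlation). NC-up library 1 stood apart for Oasl1 (117 against 55.5 and 54.5) and Rsad2 (320 against 216 and 172), which lost their calls in 8 and 6 alternatives. Usp18 (-0.76 ± 0.27 SE) and Oas3 (-1.61 ± 0.57 SE) did not pass, but passed in 7 and 10 alternatives. In edgeR Oas3 passed (adjusted p = 0.0240) and Usp18 did not (adjusted p = 0.228). The same NC-up library stood apart for Usp18 (287 against 103 and 118). After GC correction Rsad2 alone fell (-0.69), with Oasl1 at -0.79 (adjusted p = 0.128). Among tissue lists, 4 of 13 skeletal muscle genes fell, Eno3, Atp2a1, Acta1 and the myosin Myh4 (-2.53 ± 0.72 SE), and 5 of 10 epithelial and keratinocyte genes fell, including Lor, Krt14, Krt1 (-1.15 ± 0.32 SE) and Krt10 (-1.06 ± 0.27 SE). Adjusted over the list alone, 4 muscle genes fell and 1 rose, and 5 epithelial genes fell. After GC correction 3 fell in each. NC-up library 1 was the lowest of its group for the 4 epithelial genes, with Krt10 at 84.8 against 227 and 198 (79.8, 84.4 and 61.6 in SETDB2-up), Lor at 53.0 against 110.1 and 173, and Krt1 at 32.8 against 63.2 and 63.5. Myh4 had overlapping values (10.6 in an NC-up library, 26.8 in a SETDB2-up library), did not pass in edgeR (-2.52, adjusted p = 0.255) or after GC correction (-2.47, 0.0574) and lost its call in 14 alternatives. Their camera adjusted p was 0.00964 and 0.0397, against adjusted p = 0.840 with an estimated correlation.

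In the protocadherin clusters 22 of 57 members fell and 1, Pcdhb16 (0.75), rose (the same adjusted over the list alone; camera adjusted p = 0.0140, against adjusted p = 0.840 with an estimated correlation). The members that fell belong to the gamma cluster, such as Pcdhgb8 (-0.49 ± 0.08 SE), Pcdhga12 (-0.27 ± 0.06 SE), Pcdhga6 (-0.26 ± 0.06 SE) and Pcdhgc5 (-0.26 ± 0.06 SE). They share constant exons, so their reads are not independent. Before GC correction the list's median was 0.01, opposite in sign to its test. After it 8 fell and none rose, and the median was -0.06. Of 4 Y-linked genes Kdm5d (0.51 ± 0.13 SE) and Uty (0.50 ± 0.13 SE) rose, the same adjusted over the list alone (camera adjusted p = 0.0484, against adjusted p = 0.840 with an estimated correlation). Eif2s3y (0.19 ± 0.10 SE) and Ddx3y (0.15 ± 0.09 SE) did not pass and turned negative after GC correction, where none of the 4 passed and the list's adjusted p was 0.569. These 12 lists, 10 lower and 2 higher, were those past camera's preset correlation; none passed with an estimated correlation at an adjusted or unadjusted p under 0.05. By fry none passed adjustment (smallest adjusted p = 0.178, with 14 at an unadjusted p under 0.05), and 36 passed fry's test for change in either direction.

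**Figure D5:**
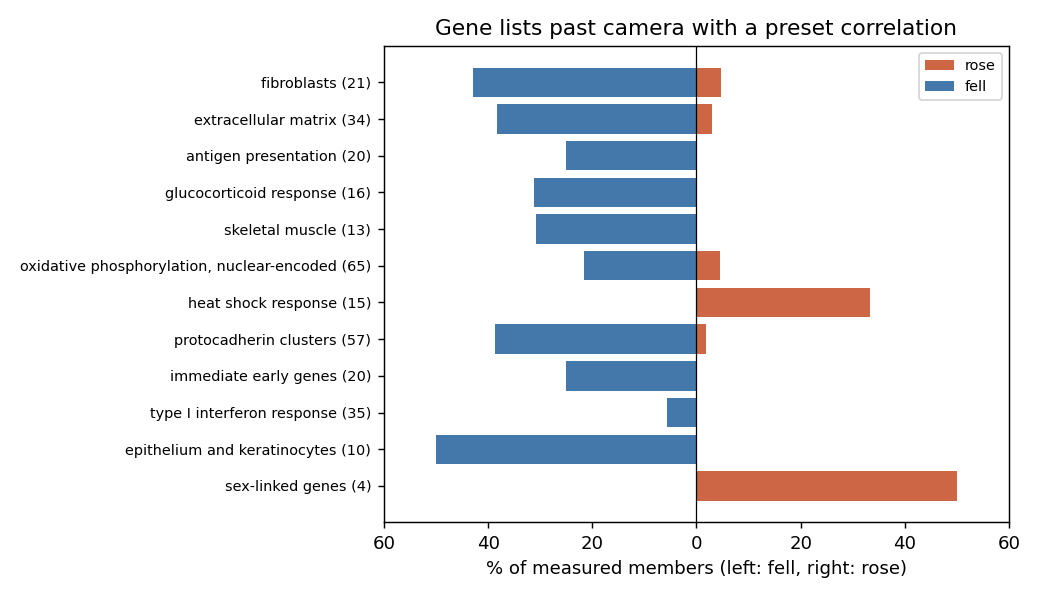
Percent of measured members (x axis) that fell (blue, to the left) or rose (orange, to the right) at an adjusted p under 0.05 in the 12 lists past camera with a preset correlation; the number measured is in parentheses. The heat shock and sex-linked lists point to the right and the other 10 mainly to the left, with 13 of 34 extracellular matrix genes falling.

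The remaining 40 lists did not pass camera, with adjusted p from 0.0983 to 0.992. After GC correction 7 of them passed camera with a preset correlation: glycolysis and hypoxia (adjusted p = 0.00285), the genes of the series title (0.00929), Kruppel-like factors (0.0121), cholesterol synthesis (0.0142), unfolded protein (0.0158), neuropeptides (0.0195) and erythroid genes (0.0350). With an estimated correlation, run on uncorrected values only, glycolysis and hypoxia had an adjusted p of 0.891 and the other 6 of 0.840. Among neuropeptides 4 of 15 rose and none fell (the same adjusted over the list alone): Calca, Tac1, which encodes substance P (0.37 ± 0.06 SE), Nts, which encodes neurotensin (1.34 ± 0.26 SE, from 58.0 to 153 normalised reads), and Scg2, a granin (0.26 ± 0.06 SE); after GC correction Scg2 did not pass (0.18). Among 15 peptidases that degrade neuropeptides Ide and Ece1 (-0.21 ± 0.07 SE) fell and Lnpep (0.62 ± 0.10 SE) rose, and Ece1 did not pass after GC correction (-0.11). In prohormone processing the convertase Pcsk1 (0.47 ± 0.07 SE) and Ctsl (0.20 ± 0.06 SE) rose and Pcsk1n, which encodes an inhibitor of that convertase, fell (-0.50 ± 0.07 SE), out of 9; after GC correction Ctsl did not pass (0.07). Of 12 CGRP and related receptors Oprm1, the mu-opioid receptor, rose (0.41 ± 0.14 SE), and none adjusted over the list alone or after GC correction (0.35). Among 21 genes of the H3K9 methylation machinery 3 rose and 2 fell, with Trim28 at -0.28 ± 0.06 SE, Kdm7a at 0.33 ± 0.09 SE and Cbx5 at 0.24 ± 0.07 SE. After GC correction none rose and 2 fell, and Trim28 (-0.07, adjusted p = 0.531), Kdm7a (0.13, 0.356) and Cbx5 (0.08, 0.462) did not pass. Of 13 Kruppel-like factors 5 fell and none rose, including Klf2 (-0.65 ± 0.14 SE), Klf4 and Klf5 (-0.40 ± 0.09 SE), and 3 fell after GC correction, without Klf2 (-0.38, adjusted p = 0.108). Among 32 nociceptor ion channels Scn9a (0.28 ± 0.06 SE) and Trpa1 (0.29 ± 0.08 SE) rose and Hcn2 (-0.52 ± 0.06 SE) fell. After GC correction none of the 32 passed, with Scn9a at 0.11 (adjusted p = 0.232), Trpa1 at 0.13 (0.310) and Hcn2 at -0.14 (0.139). Of 25 migraine susceptibility genes 3 rose, Plce1 (0.36 ± 0.07 SE), Calca and Scn1a (0.32 ± 0.07 SE), and 1 fell; after GC correction 2 rose, without Scn1a (0.17), and none fell.

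Pan-neuronal genes held 2 that rose and 4 that fell of 17, with Rbfox3 at -0.38 ± 0.06 SE, Tlx3 at -0.40 ± 0.08 SE and Pou4f1 at -0.28 ± 0.06 SE. After GC correction 3 rose and 3 fell, Rbfox3 was at -0.19, Pou4f1 at -0.30 and Tlx3 at 0.04 (adjusted p = 0.777). Of 14 peptidergic nociceptor genes Calca and Tac1 rose. In non-peptidergic nociceptors Nts alone of 22 rose, in C-fibre low-threshold mechanoreceptors Cdh9 alone of 8 rose (0.86 ± 0.19 SE), and none of 6 cold-sensing genes passed, with Trpm8 at 0.15 ± 0.06 SE. For the last 4 of these lists the counts were the same after GC correction. Of 22 markers of large myelinated neurons 5 rose, including Spp1 (0.45 ± 0.07 SE) and Ntrk2 (0.25 ± 0.06 SE), and 1 fell; after GC correction 2 rose and none fell. Synaptic genes rose in 6 and fell in 2 of 25, with Rab3c at 0.36 ± 0.06 SE and Sv2c at 0.31 ± 0.06 SE, and in 3 and 1 after GC correction. In the nerve injury list Nts rose and Jun fell out of 19; 3 rose and 1 fell after GC correction. In glia, 3 of 16 satellite markers rose and 2 fell, with Cdh19 up and Sox10 (-0.46 ± 0.06 SE) down, and 2 rose and 1 fell after GC correction. Of 20 myelinating Schwann markers 1 rose and 4 fell, including Mag, the myelin-associated glycoprotein (-0.33 ± 0.07 SE), and none fell after GC correction, where Mag was at -0.16. Of 11 other Schwann markers Scn7a (0.39 ± 0.06 SE) and Chl1 (0.37 ± 0.07 SE) rose and Ngfr (-0.19 ± 0.05 SE) fell; after GC correction Chl1 (0.17, adjusted p = 0.131) and Ngfr (0.00, 0.994) did not pass.

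Among vascular and blood lists, 3 of 20 endothelial genes fell, Cldn5 (-0.40 ± 0.08 SE), Plvap (-0.91 ± 0.21 SE) and Egfl7 (-0.33 ± 0.09 SE); Plvap lies opposite the more abundant Gtpbp3. After GC correction none of the endothelial genes passed, with Cldn5 at -0.16 (adjusted p = 0.226), Plvap at -0.67 (0.0525) and Egfl7 at -0.18 (0.211). Of 12 pericyte and smooth muscle genes Rgs5 rose (0.19 ± 0.06 SE) and Myl9 fell (-0.27 ± 0.08 SE), neither after GC correction (0.01 and -0.13). Of 9 erythroid genes only Hba-a2 fell, and it lost its call in 7 alternatives. Its values were 236, 321 and 743 in SETDB2-up libraries 1 to 3 and 1239.5, 2033 and 1003 in NC-up libraries 1 to 3. Of 22 macrophage genes Lyz2 rose (0.53 ± 0.15 SE) and C1qc fell (-0.51 ± 0.11 SE). After GC correction Lyz2 (0.48, adjusted p = 0.0768) and C1qc (-0.34, 0.0956) did not pass, and Lyz2, whose values overlapped between the groups, did not pass in edgeR (0.53, 0.333). None of 4 T and NK cell, 4 B cell, 8 neutrophil, 7 mast cell or 12 central nervous system markers passed, with Lck at -0.23 ± 0.33 SE, Ighm at -0.12 ± 0.13 SE, S100a9 at 0.83 ± 0.53 SE, Mcpt4 at -0.51 ± 0.27 SE and Gfap at -0.21 ± 0.10 SE. Of 16 complement genes C3 rose (0.94 ± 0.27 SE) and C1qc fell, and of 14 NF-kB targets Nfkbia (-0.54 ± 0.09 SE) and Relb (-0.43 ± 0.13 SE) fell; Relb did not pass after GC correction (-0.29). C3, which liver also makes, overlapped between the groups, with 233, 418 and 129 against 99.6, 115 and 153, highest in the SETDB2-up libraries with liver transcripts, and did not pass in edgeR (1.07, adjusted p = 0.261). Of 6 adipocyte genes Plin4 and Pck1, a gluconeogenic enzyme that liver also makes, rose. Pck1 was high in SETDB2-up libraries 1 and 2 alone (62.7, 110.9 and 1.78 against 2.12, 3.83 and 1.79), and did not pass after GC correction although its fold was as large (3.02, adjusted p = 0.0758). Of 6 pituitary genes Tshb fell (-1.33 ± 0.40 SE), and of 9 bone and cartilage genes Spp1 rose and Alpl (-0.74 ± 0.11 SE) and Col2a1 (-0.69 ± 0.20 SE) fell, Col2a1 not after GC correction (-0.40).

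In metabolism, the unfolded protein list held 6 of 24 that rose, such as Pdia6 (0.44 ± 0.07 SE) and Hsp90b1 (0.38 ± 0.06 SE), both in the endoplasmic reticulum, and 1 that fell. Ribosomal protein genes went both ways, 14 rising and 11 falling of 77, with Rps29 (-0.89 ± 0.07 SE), Rps28 (-0.64 ± 0.08 SE) and Rps21 (-0.56 ± 0.07 SE) falling furthest. Cholesterol synthesis held 1 rise, Idi1 (0.36 ± 0.08 SE), and 5 falls of 24, with Srebf2 at -0.29 ± 0.06 SE. Glycolysis and hypoxia held 4 rises, including Gapdh (0.30 ± 0.06 SE), and 2 falls of 27, including Vegfa (-0.31 ± 0.08 SE). The circadian list held 4 rises, including Nr1d2 (0.44 ± 0.09 SE), and 3 falls of 19, including Per1. Bub1b was the only cell cycle gene of 28 to pass (0.73 ± 0.22 SE). After GC correction the rises and falls were 3 and 1 in unfolded protein, 10 and 9 in ribosomal proteins, 0 and 4 in cholesterol synthesis, 5 and 1 in glycolysis and hypoxia, 3 and 2 in the circadian list, and 0 and 0 in cell cycle. Idi1 (0.18), Srebf2 (-0.11) and Bub1b (0.73, a fold as large) did not pass then. Adjusted over the list alone, the counts of these 40 lists changed in 13. Rises became 7 in large myelinated neurons, 4 in satellite glia, 3 in adipocytes, 3 in prohormone processing, 1 in NF-kB targets and 0 in CGRP receptors and cell cycle. Falls became 6 in Kruppel-like factors, 7 in cholesterol synthesis, 5 in myelinating Schwann cells, 4 in the circadian list, 2 in migraine genes and 13 in ribosomal proteins.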

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

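Corrections for GC content, removal of both SETDB2-up libraries with liver transcripts, robust limma and removal of opposite-strand or liver genes were chosen after the data were examined. The count of genes changed between SETDB2-up and NC-up, 2690, became 957 after GC correction, 1173 after GC and length correction, 540 without both SETDB2-up libraries 1 and 2 (1 library left, so the spread is that of NC-up), 176 with a 2-fold minimum and 262 at an unadjusted p with that minimum. Leaving out a library gave 1093 (without SETDB2-up library 1) to 3333 (without SETDB2-up library 3), and 1573 and 1611 without SETDB2-up or NC-up library 2; fewer samples lower the power of each such fit. Restricting the uncorrected test to genes with a GC value left 2584, so the loss after correction does not come from the genes removed. Tests of recovered reads gave 2865 (edgeR, TMM), 2797 (DESeq2) and 2599 (limma-voom). Setdb2 was no longer past the threshold at 0.49 after GC correction, 0.50 after GC and length correction, 0.49 after GC correction with the replicate block and 0.65 without both SETDB2-up libraries 1 and 2; the correction lowered its fold, and the cause for the others was not tested beyond having fewer samples. Leaving out a library, Setdb2 ranged from 0.56 to 0.71, with the call lost without NC-up library 2 or any of the SETDB2-up libraries. Klf4 ranged from -0.96 to -0.58, Ide from -0.94 to -0.76 and Calca from 0.22 to 0.31 over 26 alternatives, all past the threshold. Calcb, never past it, ranged from -0.0578 to 0.0201 (without NC-up library 2) when a library was left out and was 0.0437 without both SETDB2-up libraries 1 and 2. Eif2s3y turned to -0.0473 after GC correction, -0.0367 after GC and length correction, -0.0473 after GC correction with the replicate block and -0.0662 without both SETDB2-up libraries 1 and 2, and Ddx3y to -0.0918, -0.0841, -0.0918 and -0.0118; neither had passed.

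The gene lists moved, 12, became 0 in camera with an estimated correlation and 0 by fry, ranged from 7 (without NC-up library 2) to 11 when a library was left out, and were 17 after GC correction, 10 of them shared. For the other 70 named genes, 1529 of 1732 values kept direction and side of the threshold, 177 lost the call, 18 gained it and 8 changed sign. The labels do not say whether the numbers pair the samples. Deviations of same-numbered libraries correlated at 0.06, 0.04 and 0.05, and those of differently numbered libraries at -0.036 to -0.010. Every sample correlated best with its own number, a hint from the data and not the design. With the replicate number as a block, 3618 genes passed in limma, 3975 in edgeR and 1850 with GC correction, and 13 lists passed. Depth limits the low genes: 3 reads amount to 0.128 to 0.155 CPM.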

Other observations

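Tests of the GC trend within lncRNA genes and of other splits of the libraries were written before their results were seen; the tests of length, of the treatment, of Ide and its neighbours and of liver transcripts were chosen after, and the bounds for the effects of treatment and for copy number were rewritten once their values were known. Several abundant genes outside the lists fell and kept their call after GC correction, and are named here because of their values. Hnrnpa0, an RNA-binding protein, fell from 6740.3 ± 478 to 3570.4 ± 325 normalised reads (SD, n = 3 each; log2 fold change -0.92 ± 0.07 SE, limma adjusted p = 7.00e-08), and Marcks, a membrane-bound substrate of protein kinase C, from 3320.0 ± 257 to 1924 ± 339 (-0.80 ± 0.10 SE). Snrnp27, a protein of the spliceosome, fell by 0.86 on the log2 scale and Arglu1, a splicing regulator, by 0.62. The developmental transcription factors Foxd1 (-1.05 ± 0.14 SE) and Bhlhe22 (-1.21 ± 0.21 SE) fell from lower levels. Naca, a subunit of the nascent polypeptide complex, and Lars2, the mitochondrial leucyl-tRNA synthetase, rose by 0.37 and 0.52.

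Of 345 zinc-finger genes named Zfp, chosen after their values were seen, 49 rose and 17 fell, with a median log2 fold change of 0.17; their median GC content was 44.5%, against 49.9% over all genes compared. After GC correction 6 rose and 6 fell, and the median was 0.09. With and without the correction, Zfp141 (0.87 ± 0.18 SE), Zfp940 (0.81 ± 0.19 SE) and Zfp971 (0.65 ± 0.10 SE) were among those that rose. Zfp276 (-0.47 ± 0.07 SE), Zfp36l1 (-0.40 ± 0.10 SE) and Zfp523 (-0.31 ± 0.07 SE) fell in both. Among lncRNA genes that lie under a more abundant gene on the opposite strand, 116 of 550 fell and 2 rose (median log2 fold change -0.22), against 12 and 16 of 381 free of overlap (median 0.08). With GC correction the falls were 44 of 327 and 6 of 260.

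Fold changes fell with GC content: across 14687 genes, which are not independent replicates, Spearman's rho was -0.57. Slopes on GC, in log2 units per 10 points of GC, were 0.09, 0.14 and 0.10 in the NC-up libraries and -0.17, -0.13 and -0.03 in the SETDB2-up libraries. Transcript length alone is argued against, since the partial rank correlation with GC given length stayed at -0.549. A library-wide GC bias that acts on any transcript may account for it, as rho was -0.368 across 260 lncRNA genes free of overlap. An effect of the SETDB2-up treatment on GC-rich genes stays open: the gap between the groups in slope was 0.946 times the largest range within a group, and no slope crossed over, so that treatment and library preparation cannot be told apart here.

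Ide fell together with Fgfbp3, Btaf1 and 4931408D14Rik. The GC trend is argued against, because Ide stood at -0.94 after GC correction, with an adjusted p of 3.14e-08. A difference in copy number of chromosome 19 segments between the animals of the groups is a candidate explanation (a duplication holding Ide and Fgfbp3 is known to segregate in C57BL/6J mice, and the labels give no strain): 2.73% of windows elsewhere that reach 500 kb to each side of a gene that fell (11 of 403) held as many genes at or below -0.5, between the bounds of 1% and 5%. Windows centred on neighbouring genes that fell overlap, so the 11 are not independent regions, and gene density was not matched. A narrower window run first (2 of 403 elsewhere held as many) was cut to the span of the genes that fell, so it restates them and is not used. Cpeb3 and Marchf5, between the genes that fell, speak against a single segment, and no DNA was measured. The falls also differed in size, from -0.63 in Btaf1 to -2.88 in 4931408D14Rik. Whether a shared change in copy number could give both was not tested. Ide was below every NC-up library in 3 of 3 SETDB2-up libraries. An effect of the SETDB2-up treatment on Ide cannot be told apart from a difference in copy number with these groups.

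Liver transcripts in SETDB2-up libraries 1 and 2 were followed with 42 liver genes listed after Alb and others had been seen, 28 of them measured and 12 of those at a mean of 10 or more in the NC-up libraries. An effect shared by the SETDB2-up group is argued against: over the 23 genes raised at least 4-fold in both libraries, library 3 had a median of 1.40 times the NC-up mean (1 added to each value). RNA from liver in SETDB2-up libraries 1 and 2 may account for the rises there. The reason is that many of the 23 genes kept a similar ratio between library 2 and library 1. The median ratio was 2.41 after subtracting the NC-up mean, with an interquartile range of 0.575 on the log2 scale. Single genes lay further out, with log2 ratios from 0.23 (Bhmt) to 2.94 (Serpina1e). Alb stood at 3769.5 and 1673, Apob at 1159.5 and 450.3 and Mup3 at 585 and 189. The 28 genes held 0.0474% and 0.0732% of the reads there and 0.0255% to 0.0317% in the other libraries. Most of the list's reads in the NC-up libraries came from Trf, which was not raised. Trf had 4192 to 5218.5 normalised reads in NC-up and 3972 to 5304 in SETDB2-up. The shares therefore understate the contrast for the raised genes. Without liver genes 2699 genes changed. That left 16359 of 16387 genes in the test, so the count could move little. It cannot show how far the wider count depends on RNA from liver in libraries 1 and 2.

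Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. Apart from the real split, each mixes libraries of both groups. A difference between the groups then widens the spread within each part and lowers the count of genes, so these counts do not measure a chance level. The real split gave 2690 changed genes and the highest of the other 9 gave 0 in limma and 0 in edgeR (158 to 1098 at an unadjusted p under 0.05 in limma); 1 of 10 splits was as large. For gene lists the real split gave 12 and the others 7 to 16, the highest being 16; 7 of 10 splits gave as many. The count of lists past camera with a preset correlation thus did not set the real groups apart.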
